A study of Mus musculus with 12 samples.

How the data were processed

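RNA was taken from 6000 sorted peritoneal B1b cells per mouse and amplified with a low-input SMART-Seq v4 kit, which does not mark strand, per the labels' protocols. There were 7 Xbp1dIEC and 5 WT libraries, grouped by the genotype in the labels. The labels give no sex, litter or day, and p-values measure the spread between these mice as labelled. Per the submitters' processing notes, Trim Galore 0.4.4, STAR 2.5.2b and DESeq2 1.18.1 were used, with the build GRCm38.p5. The deposited values are raw counts of reads per gene in the layout that STAR writes, with 1 unstranded column and 2 stranded columns, and the authors did not normalize them.

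The unstranded counts were used. Rows for unmapped, multimapping, ambiguous and unassigned reads were kept out of library sizes and tests and were used only as measures of composition. Of 53465 gene identifiers, 53360 matched GENCODE M21 on GRCm38, which gave symbols and coordinates, and 105 did not. Reads that map to several places are not in the counts, so genes with near-identical copies, such as ribosomal protein and immunoglobulin genes, are undercounted to an unknown degree. Overlapping and antisense genes cannot be told apart without strand.

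Genes were filtered with filterByExpr of edgeR 4.0.16 at its default minimum of 10 counts, scaled with TMM and tested with the quasi-likelihood test in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 CPM used a prior count of 2. The 27 gene lists were fixed before the data were examined, and 24 had at least 3 measured members. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, beside an estimated correlation and fry. Shares and composition were compared by a two-sided exact permutation test over all 792 splits of the libraries, adjusted within each family of measures. Pairs of libraries were compared by a chi-square per degree of freedom over genes to look for repeated deposits. The lowest was 16.4, so each library was counted once.

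The genes named were chosen by a rule fixed before the data were examined. It takes up to 12 genes of smallest p in each direction past the threshold and, where fewer than 10 pass, the 10 genes of smallest p, without immunoglobulin segments, predicted genes and pseudogenes. It adds list members past the threshold, up to 3 members of smallest p of each list described, and a fixed set of B cell and sorting markers.

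The test was run on simulated counts with the means, library sizes and spread of these libraries and 200 changed genes, over 13046 genes. It recovered 18.5% of genes changed by a fold of 2, 73.0% of those changed by 4 and 93.3% of those changed by 8, and called 3 unchanged genes. Each gene was drawn independently, without the differences that the real libraries share across genes, so these rates may not hold for the real libraries.

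Alternatives fixed before the data were examined were other scalings (size factors of DESeq2 1.42.0, upper quartile, library size only, immunoglobulin genes left out), other filters, DESeq2, limma-voom with and without quality weights, robust dispersion, the stranded columns, a threshold of 0.10, a replicate block, covariates for macrophage markers and for sex-linked transcripts, a surrogate variable from sva 3.50.0, and leaving out each library. Chosen after seeing the data were a covariate for mitochondrial ribosomal RNA, alone and with the sex-linked one, and fits of the libraries with under 1% mitochondrial ribosomal RNA and of those with Y-linked transcripts. Gene length was the union of annotated exons.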

Results

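Gene expression was measured by RNA sequencing in peritoneal B1b cells, an innate-like B cell subset of the body cavities, from 12 germ-free C57BL/6 mice aged 10 weeks. In 7 mice Xbp1, a transcription factor of the unfolded protein response, was deleted in intestinal epithelial cells (Xbp1dIEC), and 5 mice were wild type (WT). Each library came from 6000 sorted live cells that were CD19+ and lacked CD23, CD5, CD3 and F4/80. The libraries held 18940638 to 33988670 counts in genes, with a median of 25701974.5. The comparison asked whether B1b cells of the cavity differ when the gut epithelium lacks Xbp1. The series title links epithelial endoplasmic reticulum stress to an IgA response.

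The libraries also differed from each other within each genotype. Mitochondrial ribosomal RNA took 2.47% to 5.11% of counts in 5 libraries (Xbp1dIEC replicates 2, 3, 4 and 7 and WT replicate 2) and 0.315% to 0.725% in the other 7. In those 5 libraries 20.1% to 22.5% of reads mapped to several places, against 9.26% to 16.0% in the other 7. The first principal component of log2 CPM (counts scaled to a common library size) held 47.5% of the variance and parted the libraries in the same way. Y-linked transcripts were present in 4 WT and 3 Xbp1dIEC libraries, and Xist, the transcript of the inactive X chromosome, in 1 WT and 4 Xbp1dIEC libraries. WT replicate 2 was both the WT library with Xist and the WT library with high mitochondrial ribosomal RNA.

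**Figure D1:**
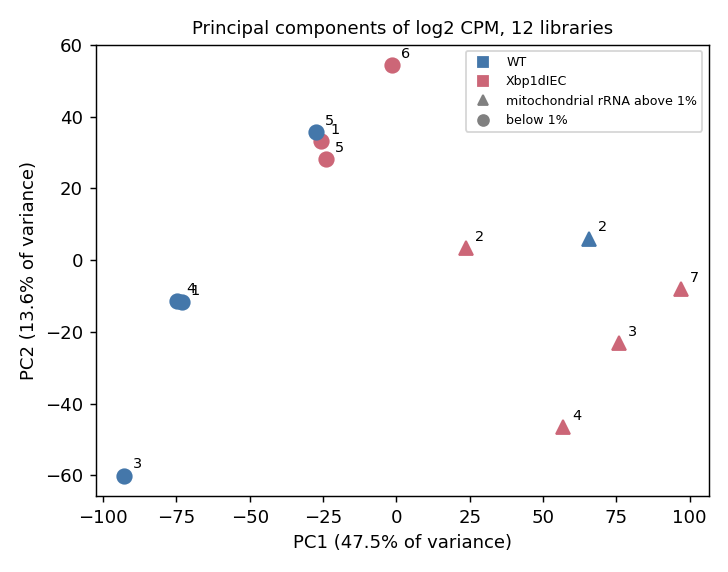
Principal components 1 and 2 of log2 CPM of the tested genes, 1 point per library, coloured by genotype and numbered by replicate. Triangles are the 5 libraries with more than 1% mitochondrial ribosomal RNA, and they lie at the right of component 1, WT replicate 2 among them.

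In Xbp1dIEC mice, 3 genes were higher and 1 was lower than in WT among 13324 genes tested. Gh, which encodes growth hormone, stood at 4.27 ± 1.20 CPM in WT (SD, n = 5) and 18.5 ± 4.78 CPM in Xbp1dIEC (SD, n = 7). Its log2 fold change was 2.12 ± 0.26 (SE), with an adjusted p of 0.0124 in edgeR's quasi-likelihood test. Cbr3, a carbonyl reductase, rose from 3.30 ± 0.527 CPM to 14.6 ± 5.07 CPM, a log2 fold change of 2.14 ± 0.28 with an edgeR adjusted p of 0.0124. Arrdc5, an arrestin domain gene, had 160 counts over the 7 Xbp1dIEC libraries, from 3 to 47 in each, and 1 count over the 5 WT libraries. The ratio of its counts was 161.5 after library size, with a 95% interval of 28.6 to 6419 that covers counting error only, and its edgeR adjusted p was 0.0124. Tnfrsf19, a receptor of the TNF receptor family, fell from 14.7 ± 8.57 CPM to 1.78 ± 0.783 CPM, a log2 fold change of -3.03 ± 0.44 with an edgeR adjusted p of 0.0226. For each of these 4 genes, all 7 Xbp1dIEC libraries lay beyond all 5 WT libraries.

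**Figure D2:**
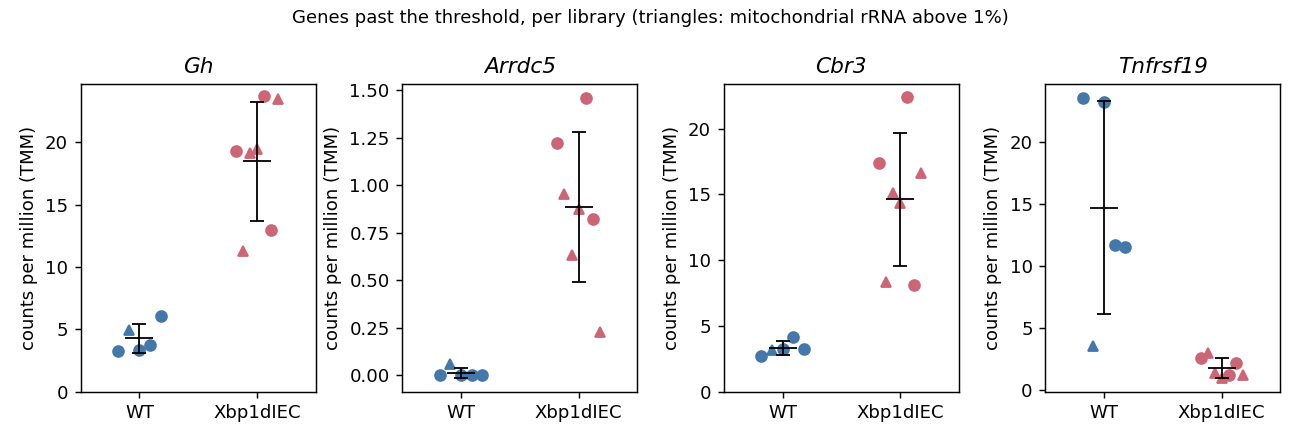
TMM-scaled CPM of the 4 genes past the threshold in each of 5 WT and 7 Xbp1dIEC libraries. Bars are the mean and SD, triangles are the libraries with more than 1% mitochondrial ribosomal RNA, and the groups do not overlap in any of the 4 genes.

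On GRCm38, Gh lies on chromosome 11 from 106300271 to 106301865, on the same strand as Cd79b, an abundant B cell receptor gene at 106311341 to 106314762 whose 3' end faces Gh. Cbr3 lies on chromosome 16 from 93683215 to 93690990, Arrdc5 on chromosome 17 from 56294111 to 56300286 and Tnfrsf19 on chromosome 14 from 60963875 to 61046490. All 4 are protein-coding, and the counts are sums over their exons without strand.

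These calls depended on which libraries were included. Without WT replicate 1, 3 or 4 no gene passed, and without WT replicate 5 a single gene passed. Without WT replicate 2 the count rose to 3718 genes, 1858 higher and 1860 lower, with all 4 genes among them. Without Xbp1dIEC replicate 3, 4, 5 or 7 the 3 higher genes passed and Tnfrsf19 did not. Without Xbp1dIEC replicate 2 or 6, 12 and 11 genes passed, and without replicate 1 the count stayed at 4. DESeq2 called 484 genes and limma-voom with quality weights 5699. With the macrophage marker level as a covariate 0 of 15104 genes passed, with edgeR adjusted p of 0.140 to 0.252 for the 4 genes. The log2 fold changes moved little, to 2.04 ± 0.31 for Gh, 1.94 ± 0.33 for Cbr3 and -2.73 ± 0.53 for Tnfrsf19, and that of Arrdc5, which rests on 1 WT count and the prior count, from 6.32 to 6.20, with larger standard errors than without the covariate for Gh, Cbr3 and Tnfrsf19. Within the 7 libraries with little mitochondrial ribosomal RNA (3 Xbp1dIEC and 4 WT) and within the 7 with Y-linked transcripts (3 and 4), 0 genes passed in edgeR, and 4541 and 3971 genes had an unadjusted p under 0.05. The 4 genes had edgeR adjusted p of 0.0773 and 0.105 there, with log2 fold changes of 2.19 ± 0.31 and 1.81 ± 0.33 for Gh, 2.26 ± 0.34 and 1.74 ± 0.35 for Cbr3 and -3.13 ± 0.41 and -2.78 ± 0.37 for Tnfrsf19. Arrdc5 had no counts in the WT libraries there, so no fold is given. In all 12 libraries 2830 genes, or 21.2%, had an unadjusted p under 0.05, 1050 higher and 1780 lower.

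The genes next in order did not pass the threshold, and most had lower values in Xbp1dIEC. Rasgef1b, a Ras exchange factor, had a log2 fold change of -1.29 ± 0.21 and an edgeR adjusted p of 0.0775. St8sia6, a sialyltransferase, had -1.48 ± 0.25 and 0.0870. Tent5c, Neurl3 and Cdc25b had log2 fold changes of -1.91, -1.19 and -1.26, and Optn stood at 10.6 ± 1.27 CPM in WT and 5.28 ± 0.742 CPM in Xbp1dIEC, with edgeR adjusted p from 0.152 to 0.160.

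Xbp1 itself did not differ in the B1b cells, where the allele is not deleted. It stood at 108 ± 33.1 CPM in WT and 102.0 ± 34.2 CPM in Xbp1dIEC, a log2 fold change of -0.09 ± 0.26 with an edgeR adjusted p of 0.845. The libraries carried transcripts of the sorted population and also of some markers that the sort excluded. Cd19 stood at 908 ± 211 CPM in WT and 765 ± 169 CPM in Xbp1dIEC. Cd9, a surface marker of B1 cells, stood at 177 ± 42.0 and 174 ± 66.5 CPM, Spn at 8.43 ± 2.46 and 11.1 ± 5.13 CPM, and Itgam at 23.9 ± 11.7 and 13.5 ± 5.05 CPM. Cd5 was near the floor at 0.894 ± 0.265 and 0.422 ± 0.354 CPM, and Cd3e was too low to test, with 6 counts in WT and 34 in Xbp1dIEC. Of other markers that the sort excluded, Adgre1, which encodes F4/80, was measured at 86.3 ± 12.1 and 62.0 ± 24.4 CPM. Fcer2a, which encodes CD23, was measured at 81.9 ± 7.33 and 41.1 ± 15.2 CPM. None of these genes passed the edgeR test.

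IgA and the genes around it did not pass the threshold. Igha took 0.259% ± 0.101 of heavy chain constant region counts in WT (SD, n = 5) and 0.190% ± 0.0462 in Xbp1dIEC (SD, n = 7; exact permutation p = 0.139, adjusted over 9 measures 0.758). As a gene it stood at 37.8 ± 11.3 and 24.3 ± 5.69 CPM, with an edgeR adjusted p of 0.167. Ighm took 92.6% ± 3.78 and 90.9% ± 3.83 of those counts and Ighd 6.38% ± 3.66 and 8.13% ± 4.01. None of the 9 isotype measures passed, with exact permutation p from 0.139 to 0.955. The use of variable segments did not pass either. The 10 most abundant Ighv segments held 45.5% ± 1.54 of Ighv counts in WT and 45.1% ± 2.59 in Xbp1dIEC (exact permutation p = 0.813), and the Shannon entropy of Ighv counts was 5.64 ± 0.0439 and 5.65 ± 0.0843 bits (exact permutation p = 0.884). Variable segments are short and alike, so reads shared between them leave these values uncertain. Aicda, the enzyme of class switching, stood at 23.3 ± 5.30 and 27.1 ± 7.25 CPM with an edgeR adjusted p of 0.543. Of 20 measured genes for IgA class switching, 8 had higher and 12 lower values in Xbp1dIEC (camera adjusted p = 0.229, mixed fry adjusted p = 0.0318). None passed over all genes tested and 1 was lower when adjusted over the list alone. Of the 20, 5 were lower at an unadjusted edgeR p under 0.05. Of all genes tested, 21.2% had such a p. The mixed fry test does not compare a list with other genes, and it passed 16 of 24 lists. The list's members of smallest p were Il5ra, the interleukin-5 receptor, with a log2 fold change of -0.98, Smad4 with -0.71 and Tgfbr2 with -0.97.

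The plasma cell programme did not pass camera as a list (adjusted p = 0.169). It passed the mixed fry test (adjusted p = 0.00883), as 16 of the 24 lists did. Of 19 measured members, 7 had higher and 12 lower values, and 2 were lower when adjusted over the list alone. Prdm1, the transcription factor of antibody-secreting cells, had a log2 fold change of -1.79 ± 0.38, Irf4 of -1.03 ± 0.25 and Creb3l2 of -1.09 ± 0.36, with edgeR adjusted p of 0.160, 0.162 and 0.166. Sdc1 had -1.19, Jchain -0.47 and Mzb1 0.51. The unfolded protein response list, which holds chaperones of the endoplasmic reticulum and targets of this response in general, had 15 of 24 measured members higher and 9 lower (camera adjusted p = 0.649). Manf had a log2 fold change of 0.81, Syvn1 of -0.76 and Edem1 of -0.59, none past the edgeR threshold.

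Of 24 gene lists tested, 7 passed the camera test with its preset correlation, and 0 passed with an estimated correlation. In Xbp1dIEC, 4 lists were higher. All 29 measured ribosomal protein genes had higher values, with a median log2 fold change of 0.83 (camera adjusted p = 1.26e-08, adjusted p = 0.449 with an estimated correlation). Rplp0, Rpsa and Rpl5 had log2 fold changes of 0.66, 0.85 and 0.88. Of 26 oxidative phosphorylation genes, 25 had higher values, with a median of 0.84 (camera adjusted p = 7.00e-06, adjusted p = 0.449 with an estimated correlation). Atp5c1, Ndufv2 and Sdhb had 0.59, 0.70 and 0.52. All 8 measured mitochondrial transcripts had higher values, with a median of 0.84 (camera adjusted p = 0.00261, adjusted p = 0.449 with an estimated correlation), and mt-Cytb had 0.76 and mt-Nd1 0.70. The mitochondrial list no longer passed with the mitochondrial ribosomal RNA covariate, where its mean log2 fold change went from 0.92 to 0.12. Covariate and list are both RNA of the mitochondrial genome, so this outcome was partly fixed in advance. Cell cycle genes had a median of 0.42, with 19 of 25 higher (camera adjusted p = 0.00227, adjusted p = 0.482 with an estimated correlation). Birc5, a mitotic survivin, had 1.41 ± 0.36, Stmn1 1.28 ± 0.33, Ube2c 1.33 ± 0.42 and Mki67 0.06 ± 0.50. The cell cycle list no longer passed camera without WT replicate 2 (adjusted p = 0.122) or Xbp1dIEC replicate 5 (0.0569), with the macrophage covariate (0.229) or within the libraries with Y-linked transcripts (0.318). No member of these 4 lists passed over all genes tested, and 2 cell cycle genes were higher when adjusted over the list alone. The mitochondrial ribosomal RNA share differed in the same direction, at 0.852% ± 0.994 in WT and 2.57% ± 2.04 in Xbp1dIEC (exact permutation p = 0.0985, adjusted 0.222).

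In Xbp1dIEC, 3 lists were lower. Genes of follicular and marginal zone B cells had a median log2 fold change of -0.38, with 13 of 15 lower and 6 lower when adjusted over the list alone (camera adjusted p = 0.00365, adjusted p = 0.449 with an estimated correlation). Fcer2a, which encodes CD23, stood at 81.9 ± 7.33 CPM in WT and 41.1 ± 15.2 CPM in Xbp1dIEC. Cr2, the complement receptor, had a log2 fold change of -1.21 ± 0.28, S1pr3 of -1.31 ± 0.42 and Ighd of 0.14 ± 0.30. The fry test for 1 direction passed this list alone (adjusted p = 0.0117), and its mixed test, which counts members of either direction, passed 16 of the 24 lists. Macrophage markers had a median of -0.47, with 18 of 21 lower and 3 lower when adjusted over the list alone (camera adjusted p = 0.00165, adjusted p = 0.449 with an estimated correlation). Csf1r, the receptor for macrophage growth factor, had -2.08 ± 0.45, Gata6 -2.20 ± 0.56 and Alox15 -1.24 ± 0.39. The sort removed F4/80+ cells, and the summed macrophage list still stood at 4529 ± 1500 CPM in WT and 3231 ± 1740 CPM in Xbp1dIEC (exact permutation p = 0.208). The NF-kB and Toll-like receptor list had 15 of 23 members lower and 8 higher, 7 lower and 1 higher when adjusted over the list alone, and a median of -0.43 (camera adjusted p = 0.0212, adjusted p = 0.449 with an estimated correlation). Tnfaip3, Nfkb2 and Nfkbie, which NF-kB induces, had -1.48 ± 0.34, -1.12 ± 0.26 and -0.83 ± 0.20, and Ly86 and Tlr9 had 0.69 ± 0.25 and 1.83 ± 0.77. The NF-kB list no longer passed camera without Xbp1dIEC replicate 5 (adjusted p = 0.0569), with library size only (0.0544) or with the replicate block (0.0502). Within the 7 libraries with Y-linked transcripts none of these 3 lists passed camera (adjusted p = 0.102, 0.102 and 0.103), with mean log2 fold changes of -0.42 for the B2 list, -0.47 for macrophage markers and -0.22 for the NF-kB list against -0.44, -0.59 and -0.21 in all libraries.

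**Figure D3:**
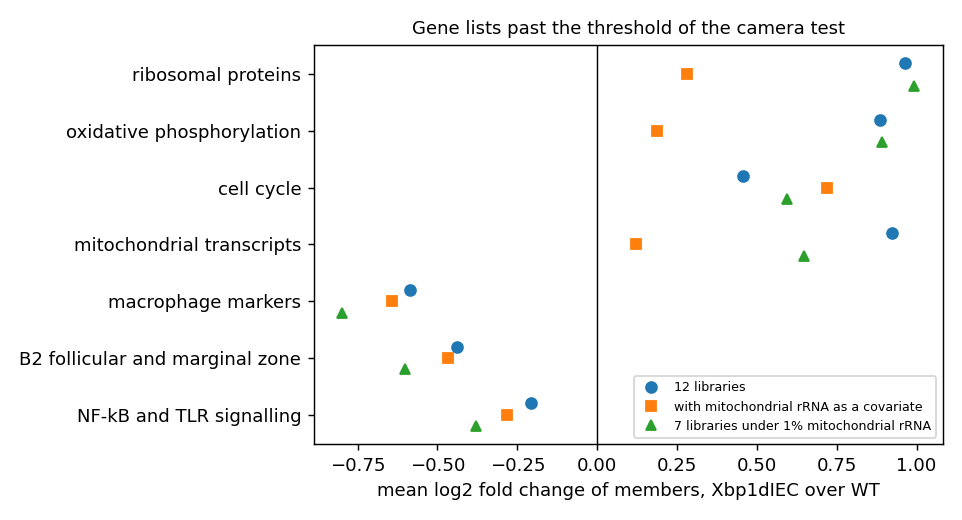
Mean log2 fold change of the members of the 7 lists past the camera test, Xbp1dIEC over WT, in all 12 libraries, with log2 mitochondrial ribosomal RNA percent as a covariate, and in the 7 libraries under 1%. With the covariate the ribosomal protein list moves from 0.96 to 0.28, and in the 7 libraries it stands at 0.99.

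B1 cell identity genes did not pass in 1 direction as a list (camera adjusted p = 0.341), with 9 of 19 higher and 10 lower. Members went both ways, and the list passed the mixed fry test (adjusted p = 0.00795), as 16 of the 24 lists did. Such a pass does not set these genes apart from other genes. Nfatc1 had a log2 fold change of -1.43 ± 0.31, Zcwpw1 of 1.36 ± 0.37 and Fcrl5, an Fc receptor-like gene, of 1.40 ± 0.39, with edgeR adjusted p of 0.160 to 0.164. The camera adjusted p was 0.0680 for heat shock and for immediate early genes, 0.130 for the type I interferon response, 0.169 for apoptosis and 0.176 for B cell cytokines. It was 0.341 for cholesterol synthesis, for homing and migration, for T and NK cell markers and for sex-linked genes. It was 0.351 for dendritic cell markers, 0.649 for the B cell core, 0.801 for glycolysis and hypoxia and 0.985 for antigen presentation. Granulocyte and mast cell, erythroid and platelet, and mesothelial markers had 0, 1 and 2 measured members and were not tested as lists.

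None of 18 measures of library composition passed after adjustment. The number of genes with at least 1 count was 19398 ± 402 in WT and 18274 ± 758 in Xbp1dIEC (exact permutation p = 0.0139, adjusted 0.159). Reads mapping to several places took 12.9% ± 4.28 and 19.0% ± 3.98 (exact permutation p = 0.0442, adjusted 0.199). The summed follicular and marginal zone list stood at 5516 ± 1190 and 3838 ± 714 CPM (exact permutation p = 0.0177, adjusted 0.159). Without WT replicate 2, 3 of the 18 passed.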

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

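The tests of the 4 genes against library quality and sex, of Ighd against Fcer2a, of the top 10 genes for WT replicate 2 and of the lists in 2 parts and against sex, the differences of Xist from Y-linked libraries, the ratios on genes picked on other libraries, the covariate fits without WT replicate 2 and the use of quartiles beside the median ratios were chosen only after the results were seen.

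A single library lay far from the others of its group in 23 of 175 values and groups looked at. The bound used gives about 1 in 20 by chance for independent, normally distributed values. Some values here are linked, as the Ighd and Ighm shares are, and some lie near 0. The count of 23 therefore cannot be set against chance. WT replicate 2 stood apart with 1463 CPM of Ighd against 657 to 841 in the other WT libraries, 12.9% Ighd and 85.8% Ighm among heavy chain counts, 40.9% lambda among light chain counts, 2.62% mitochondrial ribosomal RNA, 30.8 CPM of Zcwpw1 and 589.9 CPM of erythroid and platelet markers. It also held the single WT count of Arrdc5, at 0.0561 CPM. Xbp1dIEC replicate 2 stood apart with 0.706% Ighg2c and 0.00172% Ighe among heavy chain counts, 9.84% for the top Ighv segment, 1.89% mitochondrial protein-coding counts, 34.3 CPM of T and NK cell markers, 3.22 CPM of Tent5c, 55.8 CPM of Cr2 and 144.7 CPM of Nfatc1. Jchain reached 331 CPM in WT replicate 5 against 18.3 to 45.8 in the other WT libraries. Sdc1 reached 2.75 CPM in Xbp1dIEC replicate 1, Itgam 23.7 CPM in Xbp1dIEC replicate 7 and Ighg2b 0.206% in WT replicate 4. Granulocyte and mast cell markers reached 96.4 CPM in WT replicate 1 and 273.5 CPM in Xbp1dIEC replicate 6, which also had 15.2 CPM of mesothelial markers.

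The first pattern is the rise from 4 to 3718 genes when WT replicate 2 is left out. A wrong label of this library stays open: on 200 genes that part the genotypes among the libraries under 1% mitochondrial ribosomal RNA it lay -0.729 SD from the mean of the 4 Xbp1dIEC libraries above 1%, within their range, as a wrong label would give. It lay within that range only through Xbp1dIEC replicate 2. The mean signed log2 CPM was -0.368 in WT replicate 2, -0.709 in Xbp1dIEC replicate 2 and 0.0857 to 0.416 in Xbp1dIEC replicates 3, 4 and 7. In 7 of the 10 genes of smallest p without WT replicate 2, Gh, Cbr3 and Arrdc5 among them, it lay on the WT side of all 7 Xbp1dIEC libraries. Sex cannot be told apart from genotype for these genes: their fold changes within the libraries with Y-linked transcripts had a median ratio of 0.862 (quartiles 0.689 and 1.01) to those without WT replicate 2, but share libraries with the choice of genes, and with genes picked on the Xist libraries and measured on others the median ratio was 0.574 (0.516 to 0.622), against a median of 0.891 over the other choices of 4 Xbp1dIEC libraries. Library quality cannot be told apart either: the median ratio of 0.771 within the libraries under 1% reached the bound of 0.75 set beforehand against quality, but by less than the spread of the genes (quartiles 0.531 and 0.975), with the mitochondrial covariate it was 0.643 (0.351 and 0.889) and 0 genes passed, and with genes picked on the libraries above 1% it was 0.351, the lowest of 35 choices. Of 100 splits of the libraries into groups of 7 and 5, the real one included, 5 gave at least 4 genes. Chance therefore cannot be excluded. The other splits among these 5 gave 1369 to 4004 genes and had 0 or 4 libraries above 1% in the group of 5. Of 26 splits with 1 such library there, the highest count was 4, in the real one, and the median was 0. The split with 4004 put Xbp1dIEC replicate 1 in place of WT replicate 2. It kept WT replicates 1, 3, 4 and 5 together against most Xbp1dIEC libraries, so it cannot tell a structure of the samples from genotype.

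The second pattern is the 4 genes themselves. With the mitochondrial covariate their log2 fold changes had a median ratio of 0.993 to those without it, though Tnfrsf19 moved from -3.03 ± 0.44 to -2.34 ± 0.50 and lost its call. Within the libraries with Y-linked transcripts the median ratio was 0.887, or 0.857 without Arrdc5, whose fold is set by the prior count there. The difference of Xist from Y-linked libraries within Xbp1dIEC was 0.59 ± 0.22 for Gh, 0.67 ± 0.34 for Cbr3 and -1.07 ± 0.14 for Tnfrsf19. Sex as the whole cause would need 5.63, 5.53 and -7.63, values taken without their own error. With the sex-linked covariate Cbr3 moved from 2.14 ± 0.28 to 1.93 ± 0.30 and lost its call (edgeR adjusted p = 0.0503). The 4 genes were picked for parting the genotypes in these same libraries, which favours genes that follow neither quality nor sex. These values were thus partly set by the choice and cannot exclude either as a cause. Reads running on from Cd79b into Gh would need Cd79b to rise alike, and the log2 fold change of Gh exceeded that of Cd79b by 1.75 ± 0.37. A change in the rate of run-on, and an effect of genotype, stay open and untested.

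The third pattern is the gene lists. Of 100 splits, the real one included, 27 gave at least 7 lists and the highest other gave 11, so chance cannot be excluded. The medians of 3 of the 4 higher lists and 3 of the 3 lower lists lay beyond the central 95% of lists matched on length and expression. Those matched lists were drawn gene by gene, without the correlation between members, estimated at 0.04 for the B2 list and 0.85 for ribosomal proteins. The range is therefore too narrow, and length bias stays open. Shorter genes had higher fold changes over all genes (Spearman's rho over genes -0.40, and genes are not independent replicates). For the 4 higher lists the mitochondrial covariate left a median ratio of 0.251, as library quality would give. For the ribosomal protein, oxidative phosphorylation and mitochondrial lists, quality and genotype cannot be told apart. Their median ratio was 0.210 under the covariate but 1.01 within the libraries under 1%. The mitochondrial list had 0.130 and 0.702, and its call ended with the covariate. That covariate comes from the same genome as this list, so the value of 0.130 was partly fixed in advance. It also enters the medians of 0.251 and 0.210. Under the mitochondrial covariate and within the libraries under 1%, the cell cycle list kept ratios of 1.58 and 1.31. These give no sign of quality as its whole cause. Its ratio was 0.447 within the libraries with Y-linked transcripts and 0.974 with the sex-linked covariate, so sex and genotype cannot be told apart. Macrophage RNA stays open for this list, with a mean log2 fold change of 0.17 with the macrophage covariate against 0.46 without. The 3 lower lists had median ratios of 1.10 with the mitochondrial covariate, 0.955 within the libraries with Y-linked transcripts and 0.916 with the sex-linked covariate. These ratios give no sign of quality or sex as the whole cause, although none of the 3 passed in the libraries with Y-linked transcripts. These fits also share libraries with the choice of lists, which favours lists that follow neither, so the ratios alone exclude neither cause. The difference of Xist from Y-linked libraries within Xbp1dIEC fell short of what sex would need by 8.98 standard errors for the B2 list, 4.26 for the NF-kB list and 2.52 for macrophage markers. These standard errors leave out the error of the needed value, so the shortfalls are overstated and sex stays open for macrophage markers. Fewer B2 cells inside the gate stay open for the B2 list, since Ighd lay 1.14 ± 0.38 above Fcer2a but its high level in these cells would hide the loss of a small share.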

How the results depend on the processing

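The fits with mitochondrial ribosomal RNA as a covariate and those within 7 libraries were chosen after seeing the data. The count of 4 genes (3 higher, 1 lower) stayed within 1.5 times with size factors of DESeq2, upper quartile scaling, robust dispersion, the stranded columns and without immunoglobulin genes. It was 2 (1 higher) with library size only, which moves the median of all genes to -0.35, and 2 (0 lower) with limma-voom. DESeq2 gave 484 (153 higher, 331 lower) and limma-voom with quality weights 5699 (2900 higher, 2799 lower). At an adjusted p under 0.10, 7 genes passed, 3 of them lower, and without a filter 2 were lower. The macrophage covariate gave 0 genes, 0 higher and 0 lower, while the log2 fold change of Gh went from 2.12 to 2.04 and that of Cbr3 from 2.14 to 1.94. The surrogate variable and the mitochondrial covariate each gave 0 lower, and the mitochondrial and sex-linked covariates together 2 lower. Within the 7 libraries with little mitochondrial ribosomal RNA and within the 7 with Y-linked transcripts, 0 genes passed, 0 higher and 0 lower. Leaving out 1 library gave 0 to 3718 genes, 0 to 1858 higher and 0 to 1860 lower. Xbp1 passed under no alternative.

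The labels do not say whether the replicate numbers pair the mice. Deviations of same-numbered libraries had correlations of 0.42, -0.01, -0.16, -0.08 and -0.02. These give no clear sign of pairs but cannot exclude them, since other differences between libraries could hide a pairing. With the replicate block over 10 libraries, 2 of 14894 genes passed, 0 higher and 2 lower. They included none of the 4 genes called in all 12 libraries. Of 27 lists, 11 passed with the block. In the same libraries without the block, 5 of 13066 genes passed, 3 of those 4 among them, and 9 of 24 lists passed. The filter keeps other genes with the block, and of the 24 lists tested in both, 9 passed in each.

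The count of 7 lists was 0 with an estimated correlation, 1 with fry for 1 direction, 16 with its mixed test, 11 without a filter and 3 in the libraries with Y-linked transcripts. The macrophage list was not tested with its own level as a covariate, since that fit fixes the outcome. No isotype or variable segment measure passed under any alternative, and 0 to 3 composition measures passed when 1 library was left out, 3 without WT replicate 2. The causes were not tested beyond the tests above. Among named genes, lists and measures, 211 values under an alternative newly passed, 68 no longer did and 0 passed with the opposite sign. In counts simulated at the spread of these libraries, with genes drawn independently, most folds of 2 were not detected. The real libraries share differences across genes, so their detection rate is not known.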

Other observations

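Some genes outside the naming rule, picked after their values were seen, had higher values in Xbp1dIEC without passing the threshold. Ccnd2, a D-type cyclin that B1 cells use, stood at 396 ± 124 CPM in WT and 1263 ± 528 CPM in Xbp1dIEC, a log2 fold change of 1.68 ± 0.33 with an edgeR adjusted p of 0.160, and all 7 Xbp1dIEC libraries lay above all 5 WT libraries. Ccl17, a chemokine, had a log2 fold change of 5.06 ± 1.05 and ranged from 0.408 CPM in Xbp1dIEC replicate 2 to 38.0 CPM in Xbp1dIEC replicate 4. Igkv8-21, a kappa chain segment, stood at 23.7 ± 10.3 and 66.9 ± 22.4 CPM with an edgeR adjusted p of 0.157, and its short sequence leaves the count uncertain.

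Light and heavy chain use varied between libraries of both genotypes. Lambda chains took 32.7% to 45.3% of light chain constant counts in Xbp1dIEC replicates 3, 4 and 7 and WT replicate 2, and Ighd took 10.9% to 13.9% of heavy chain constant counts there. These 4 libraries carried Xist and had more than 1% mitochondrial ribosomal RNA. In the other 8 libraries lambda chains took 20.3% to 29.8% and Ighd 4.04% to 6.62%, and among these were Xbp1dIEC replicate 5, which carried Xist with little mitochondrial ribosomal RNA, and Xbp1dIEC replicate 2, which had Y-linked transcripts with much of it.

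The relation of expression to gene length also parted the libraries. Over genes, Spearman's rho between exon length and the deviation of log2 CPM from its mean was 0.36, 0.53 and 0.35 in WT replicates 1, 3 and 4. It was -0.28 and -0.19 in WT replicates 2 and 5 and lay between -0.41 and -0.01 in the 7 Xbp1dIEC libraries. Genes are not independent replicates, and no test was made on these values.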
